A study of Mus musculus with 20 samples.

How the data were processed

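Messenger RNA was measured by sequencing in 20 libraries from 8 lines of mouse gastric organoids. Per the labels' protocols, organoids were grown in conditioned medium, RNA was collected with a column kit, and libraries were made from 100 ng of total RNA with an mRNA kit. Per the submitters' processing notes, bcl2fastq, STAR 2.5 and the mouse build mm9 were used. The gene annotation, the gene counter and whether strand was used are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be assigned with certainty; this bears on H2-Q4, Gsta1 and Gsta2. The deposited values are raw counts of reads per gene symbol, whole numbers with no normalization. The table held 24047 genes, of which 18180 had at least 1 count, and no row without a gene name. Of the symbols, 22452 matched a symbol and 1367 an older symbol in a RefSeq table of assembly GRCm38.p6, which was used for names only. No coordinates are given because that build differs from that of the counts.

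Groups came from the labels for genotype, dysplasia and the mode of KO. Libraries that share a title number share all of these, and were summed per line before testing; the labels do not say that lines came from separate animals, so p-values measure only the spread between these lines, which may be technical. No pair of libraries of one line agreed within sampling noise, the smallest chi-square per degree of freedom being 6.11. Library totals ran from 5.67e6 to 16.3e6 counts. At the smallest total, 1 CPM corresponds to fewer than 6 counts in that library, and statements on genes near 1 CPM rest on line sums of 22.2e6 counts or more.

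Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. In the main test, counts per line were filtered with filterByExpr, leaving 13476 genes, scaled by TMM and fitted with one mean for each combination of genotype and dysplasia, leaving 4 residual degrees of freedom. The ex vivo against in vivo comparison used one mean for each of the 5 groups, leaving 3. EdgeR's robust quasi-likelihood test was used with Benjamini-Hochberg adjustment and a threshold of 0.05. An SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-scaled line sums, and mean ± SD is over lines.

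Gene lists of pathways and cell types were fixed before the data were examined, 573 entries in 29 lists, of which 559 entries were in the table and 27 lists were tested. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Members were also adjusted over the list alone. No adjustment was made across the 27 lists, so a list with a single passing member can arise by chance. Scores are line means of log2(CPM + 1), tested by exact permutation over 70 assignments, with 8 tests in the family.

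The rule for named genes, written before the data were examined, took Trp53, then per comparison up to 10 genes with the largest rise and 10 with the largest fall among genes called over all genes, with an average log2 CPM above 2 and no overlap between the lines of the arms, judged within the dysplasia class or genotype compared and, for a mean, within each class separately, and from each list the up to 4 called members with the smallest p or, where none was called, up to 2 with the highest mean CPM; of the latter none is named. Because the main test called no gene, that second part gave none. It was applied instead, after the values were seen, to genes called by 3 further fits, which were DESeq2 on line sums, limma-voom with lines as correlated blocks (correlation 0.22), and that fit with a term for 6 libraries that stood apart (correlation 0.45). For KO against WT as a mean, Fstl1 and Slc25a23 were separated within each dysplasia class but overlapped over all 8 lines. List members were taken where called over the list alone. Gdf15, Mdm2, Gbp2 and Bst2, the genes given for single lines, and Fos, Axl, Fn1, Phlda3 and Vil1 in the ex vivo comparison were chosen after their values were seen.

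The procedures were tested on simulated data. Libraries were drawn for KO against WT over 12671 genes with 200 changed. Each gene was drawn independently, with spreads from a fitted trend and without the shifted libraries described below. Recovery in the real lines can therefore differ. There, Trp53 had a log2 fold change of -3.17 and an adjusted p of 0.74 in edgeR's test. The edgeR test on line sums recovered 64% of genes changed by a log2 fold change of 1 and 100% of those changed by 2, with 11 false calls among 175. DESeq2 on line sums made 36 false calls among 207, limma-voom 31 among 195 (over 12575 genes), and edgeR with libraries as samples 259 among 450. With no changed gene these made 0, 0, 0 and 97 calls. Camera found the changed list of 50 genes in both forms and called 0 of 20 random lists. Because the simulated genes did not vary together, this does not test whether the preset correlation of 0.01 is high enough.

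Libraries were checked for structure. Among them, 6 (300-2, 650-2, 565-3, 752-3, 794-3 and 801-3) read low for long genes relative to their line, with a Spearman correlation with log2 exon length between -0.43 and -0.61 over 10135 genes; 95.5% of tested genes had a length, from GENCODE vM21. A limit of -0.3 defined these length-shifted libraries. Whether replicate numbers pair the libraries was checked with the correlation of deviations from line means. For the dysplastic lines all 18 same-number pairs correlated above 0.1, from 0.40 to 0.79 with a median of 0.57, so the numbers were taken to pair those libraries. Different-number pairs ran from -0.74 to 0.46 with a median of -0.40. As every library numbered 3 was length-shifted and deviations were from line means, the limit of 0.1 alone does not show pairing by number. For non-dysplastic lines same-number correlations ran from -0.09 to 0.64 and the numbers do not pair them. The line sums hold 1 library of each number for every dysplastic line.

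Alternatives fixed before the data were examined were RLE scaling, DESeq2, no filter, libraries as samples with and without a replicate block, limma-voom with correlated lines, 5 group means, only the lines of a comparison, other pseudocounts, other set tests, and leaving out each line or each replicate number. DESeq2 was run on the genes that pass edgeR's filter, with its own independent filtering after that. Added after the data were seen were fits without the length-shifted libraries, the library term, sex of the line as a covariate and the 3-fit count, which without the length-shifted libraries rests on 2 fits.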

Results

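RNA-seq gene counts were obtained from 20 libraries of mouse gastric organoids, which are epithelial cultures grown in 3 dimensions from stomach tissue. The number in front of each library title names the organoid line, and the 20 libraries came from 8 lines on the BL/6 background. Lines 300 and 1269 were wild type (WT) and non-dysplastic, with 4 libraries. Lines 565 and 752 were WT and dysplastic, with 6 libraries. Among lines labelled as p53 knockout (KO), line 650 was non-dysplastic with the KO made in vivo (2 libraries), line 1270 was non-dysplastic with the KO made ex vivo (2 libraries), and lines 794 and 801 were dysplastic with the KO made in vivo (6 libraries). The series examined mRNA levels in gastric organoids with and without p53, the tumour suppressor encoded by Trp53. Library totals ran from 5.67e6 to 16.3e6 counts, and the summed totals per line from 22.2e6 to 36.9e6. Libraries of one line were summed, so that the line was the unit of replication.

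Trp53 was low in each of the 10 libraries labelled KO. It lay between 98.6 and 164 CPM (counts relative to the TMM-scaled library total) in the 10 WT libraries and between 4.43 and 33.0 CPM in the KO libraries. As a mean over lines, Trp53 was 137 ± 24.0 CPM (SD, n = 4 lines) in WT and 15.3 ± 11 CPM (SD, n = 4 lines) in KO lines. The KO lines were not alike. Relative to the WT lines of the same dysplasia class, Trp53 stood at 3.66% in line 1270, 5.03% in line 794, 16.1% in line 801 and 19.8% in line 650. The log2 fold change of Trp53 was -3.17 ± 0.60 (SE), with every KO line below every WT line, and its adjusted p over all genes in edgeR's quasi-likelihood test was 0.74. DESeq2 on line sums and limma-voom with lines as correlated blocks, with or without a term for 6 libraries that stood apart, called it in this comparison.

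**Figure D1:**
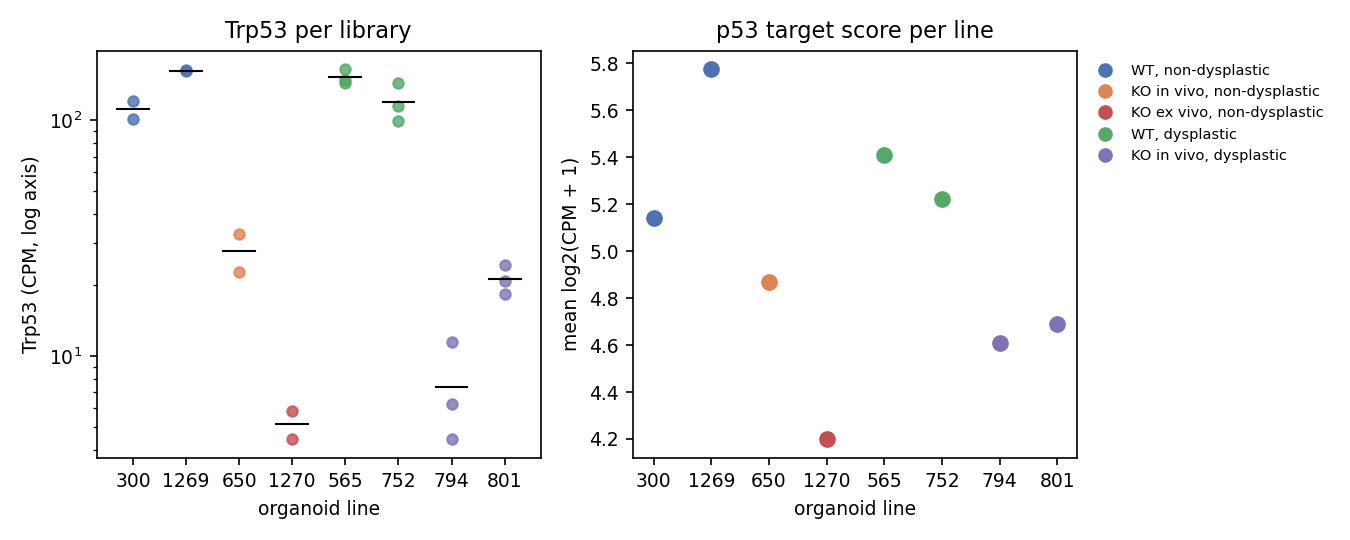
Left, Trp53 in CPM on a log axis for each library, by organoid line, with a bar at the line's mean. Right, the mean log2(CPM + 1) of the p53 target list for each line. All KO libraries lay at or below 33.0 CPM of Trp53, and the p53 target score was lower in each KO line than in each WT line.

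Genes known to be activated by p53 were lower in KO than in WT organoids. Of the 51 tested members of the p53 target list, 43 had a negative log2 fold change. Neither camera with an estimated correlation nor fry called the list, as given below. Adjusted over the list alone, 17 fell and none rose in edgeR's test, and 34 did not pass. Among those that fell were Bax, an effector of apoptosis (82.6 ± 16.1 CPM in KO and 171 ± 25 CPM in WT lines, SD, n = 4 each), Ccng1, which encodes cyclin G1 (136 ± 73.8 and 587 ± 240 CPM), Zmat3, an RNA-binding protein (37.3 ± 13.4 and 118 ± 35.7 CPM), and Ephx1, an epoxide hydrolase (91.6 ± 45.3 and 292 ± 54.4 CPM). Their log2 fold changes were -1.04 ± 0.18 for Bax, -2.12 ± 0.41 for Ccng1, -1.68 ± 0.31 for Zmat3 and -1.72 ± 0.29 for Ephx1 (SE). Mdm2, the p53-degrading ligase that p53 itself activates, fell by 1.11 ± 0.28, and Gdf15, a stress-induced secreted factor, fell by 2.41 ± 0.69 on the log2 scale. The p53 target score, the line mean of log2(CPM + 1) over the list, was 4.59 ± 0.28 in KO and 5.39 ± 0.28 in WT lines (SD, n = 4 each). The difference of -0.80 had p = 0.0286 in a two-sided exact permutation test, which is the smallest p that 70 assignments allow; adjusted over 8 such tests of scores it was 0.11, and none of the 8 passed after adjustment. Without line 1269 the exact permutation p of the score was 0.057. The number of targets that fell was 5 without line 565, 6 without line 1269, 8 without line 1270, 9 without line 794 and 28 without line 650, and 10 with sex of the line as a covariate and 27 with 5 group means.

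**Figure D2:**
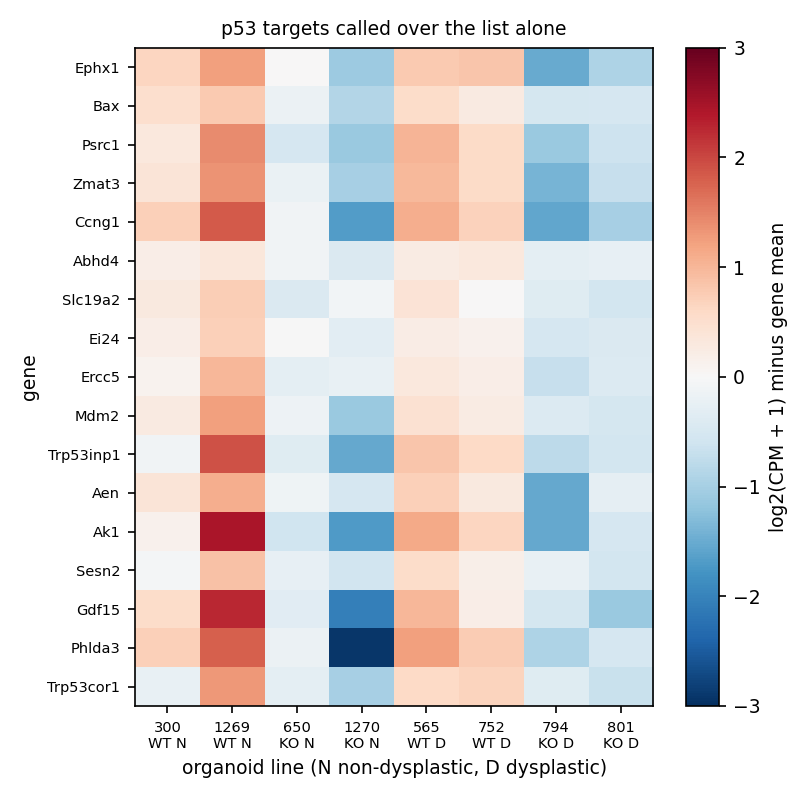
Heat map of the 17 p53 targets that fell over the list alone, as log2(CPM + 1) minus each gene's mean over the 8 lines (columns; N non-dysplastic, D dysplastic). Each WT line read above each KO line for all 17 genes.

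Cdkn2a, which encodes the cell-cycle inhibitors p16 and p19ARF, was higher in every KO line than in every WT line. It read 133 ± 105 CPM in KO and 22.2 ± 4.45 CPM in WT lines (SD, n = 4 each), a log2 fold change of 2.35 ± 0.27 (SE). It was the only one of 10 tested members of its list to pass in edgeR's test, with an adjusted p of 6.5e-04 adjusted over the list alone. In the interferon response list, 14 of 26 tested members rose over the list alone and none fell. Ifit1 rose by 2.04 ± 0.35, Rtp4 by 2.23 ± 0.41 and Isg15 by 1.98 ± 0.40 on the log2 scale (SE). The interferon score was 3.88 in line 794 and 3.13 in line 801, and between 1.90 and 2.26 in the other 6 lines, so that the difference lay in the dysplastic KO lines. The exact permutation p for KO against WT was 0.23 for this score (adjusted 0.37) and 0.40 for the antigen presentation score (adjusted 0.46). Krt5, a keratin of squamous epithelium, fell by 2.40 ± 0.53 from under 1 CPM, and Dclk1, a tuft cell marker used for gastric stem cells, rose by 1.30 ± 0.28. Each was the only member of its list to pass over the list alone, and the adjusted p over all genes in edgeR's test was 0.92 for both.

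Over all 13476 genes tested, edgeR called 0 genes between KO and WT lines, with 543 at an unadjusted p under 0.05, where chance alone gives 674. DESeq2 on the same line sums called 74, and limma-voom with lines as correlated blocks called 63. Camera with its preset correlation called 11 of 27 lists, including p53 targets and NRF2 and glutathione genes downward and interferon response and fibroblast genes upward. With an estimated correlation it called 0, at an adjusted p of 0.23 for each of those 4 lists, and fry called 0 lists.

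Because edgeR called no gene, further genes were taken after the values were seen from those called by DESeq2, by limma-voom with correlated lines and by that fit with a term for 6 libraries that stood apart. This gave 24 genes for KO against WT, 7 higher and 17 lower. Higher were Fstl1, a secreted follistatin-like glycoprotein (10 ± 8.84 CPM in KO and 0.43 ± 0.41 CPM in WT lines), Pdpn, a membrane glycoprotein (7.45 ± 5.80 and 1.65 ± 0.77 CPM), and Slc25a23, a mitochondrial carrier (32.9 ± 8.79 and 19.8 ± 5.99 CPM). Lower, beside members of the p53 target list, were Ptp4a3, a phosphatase (40.5 ± 10.6 and 110 ± 36.9 CPM), and Exoc4, part of the exocyst (51.1 ± 12.4 and 101 ± 18.2 CPM). These values are means ± SD, n = 4 lines each. The number of such genes was 42, 15, 40, 45, 4, 13, 24 and 154 without line 300, 1269, 650, 1270, 565, 752, 794 or 801, of which 4, 4, 5, 31, 1, 1, 13 and 64 were higher, so that higher genes outnumbered lower ones without line 1270 or 794; only 14 of the 24 without line 794 were shared with the 24 above. The number was 14 in the 2 of these fits that can be run without the 6 libraries that stood apart. All 10 tested members of the fibroblast list and all 13 of the mesenchymal transition list were also higher in KO, with medians of 1.61 and 0.97 on the log2 scale, and none passed over its list alone. The mesenchymal transition score was 4.57, 3.11, 4.27 and 4.63 in the KO lines 650, 1270, 794 and 801 and between 3.45 and 4.15 in the WT lines, so line 1270 read below all WT lines. The fibroblast score was 2.30, 0.91, 1.25 and 1.84 in the KO lines 650, 1270, 794 and 801 and at most 1.22 in the WT lines, and Fstl1 read 4.86, 0.58, 19.7 and 14.9 CPM in those KO lines. Other splits of the lines gave at least as many calls as KO against WT in DESeq2 and in limma-voom.

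Among non-dysplastic lines alone, Trp53 was 16.0 ± 15.5 CPM in KO and 136 ± 34.8 CPM in WT (SD, n = 2 lines each). Cdkn2a rose from 19.3 ± 2.14 to 61.5 ± 3.83 CPM (SD, n = 2 lines each), a log2 fold change of 1.67 ± 0.37. In edgeR's test its adjusted p, adjusted over the list alone, was 0.032. Krt5 fell by 3.76 ± 0.82 on the log2 scale and was the only member of its list to pass over the list alone. Of the 51 p53 targets 45 had a negative log2 fold change, with a median of -0.80, and 0 passed over the list alone. All 28 G2/M and mitosis genes and all 30 S phase genes had negative values, with medians of -0.36 and -0.37, and none of these passed over the list alone. The lines of the 2 genotypes overlapped, with KO line 650 lowest, WT line 1269 highest and KO line 1270 above WT line 300 for both scores. The G2/M score was 5.96 in KO line 650 and 6.96 in KO line 1270, against 6.44 and 7.22 in WT lines 300 and 1269. The S phase score was 5.03 and 5.93 against 5.61 and 6.22. Camera called both lists with the preset correlation, and their adjusted p was 0.60 and 0.56 with an estimated correlation. Of the 26 interferon genes 15 had positive and 11 negative values, with a median of 0.20, and 0 passed over the list alone; camera's adjusted p was 0.017 with the preset and 0.63 with an estimated correlation. EdgeR called 0 genes, with 257 at an unadjusted p under 0.05, against 6 by DESeq2 and 5 by limma-voom.

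Among dysplastic lines, interferon response genes were higher in KO than in WT. Of the 26 tested members 19 rose over the list alone, 0 fell and 7 did not pass. Ifit1, an antiviral RNA-binding protein, read 11 ± 4.60 CPM in KO and 1.10 ± 0.20 CPM in WT (SD, n = 2 lines each). Isg15, a ubiquitin-like modifier, read 9.74 ± 2.94 and 1.45 ± 0.38 CPM, Rtp4 12.5 ± 8.13 and 1.44 ± 0.22 CPM, and Usp18, which removes Isg15 from proteins, 8.62 ± 5.09 and 1.24 ± 0.17 CPM. Their log2 fold changes lay between 2.75 ± 0.57 for Isg15 and 3.31 ± 0.49 for Ifit1 (SE). In the antigen presentation list, Psmb8, an immunoproteasome subunit, rose by 1.83 ± 0.48 and the class I gene H2-Q4 by 1.04 ± 0.28, and the other 11 members did not pass. Camera called both lists upward with the preset correlation, and the adjusted p of each was 0.30 with an estimated correlation. Summed transcripts of 12 low immune cell markers were 1.70 CPM in line 794 and 3.29 CPM in line 801, against 1.89 and 2.5 CPM in WT lines 565 and 752.

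**Figure D3:**
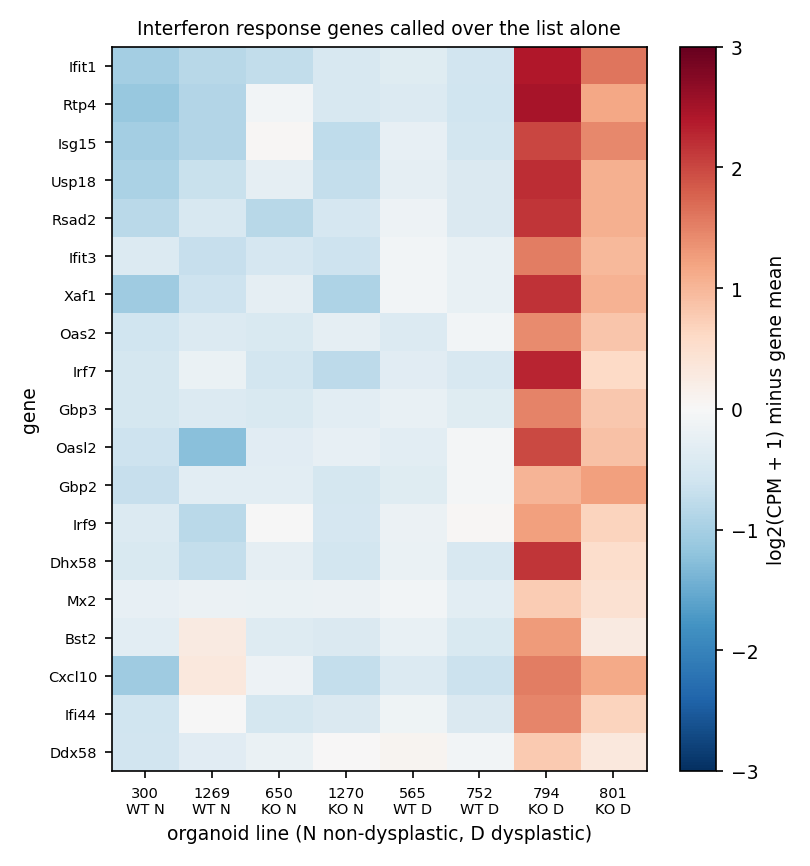
Heat map of the 19 interferon response genes that rose over the list alone between KO and WT dysplastic lines, as log2(CPM + 1) minus each gene's mean over the 8 lines (columns; N non-dysplastic, D dysplastic). Lines 794 and 801 both read above the other 6 lines except for Bst2, which was at 22.9 CPM in line 801 and 23.2 CPM in line 1269, and line 794 read above line 801 except for Gbp2.

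Genes of the NRF2 and glutathione list were lower in the dysplastic KO lines, where 6 of 24 fell over the list alone, none rose and 18 did not pass. Aldh1a1, a retinaldehyde dehydrogenase, read 88.1 ± 28.5 CPM in KO and 202 ± 13.1 CPM in WT (SD, n = 2 lines each), and the glutathione transferase Gsta1 31.7 ± 1.42 and 122 ± 59.9 CPM. Pgd, an enzyme of the pentose phosphate pathway, fell by 0.61 ± 0.17 on the log2 scale. This list, too, had an adjusted p of 0.30 with an estimated correlation, and its score had an exact permutation p of 0.20 (adjusted 0.37) between all KO and all WT lines. Cdkn2a rose from 25.1 ± 4.61 to 205 ± 112 CPM (SD, n = 2 lines each). In edgeR's test its adjusted p, adjusted over the list alone, was 0.0013. Ckmt1, a mitochondrial creatine kinase, fell by 0.86 ± 0.19 and was the only member of the parietal cell list to pass over the list alone. Among the 24 genes taken from the 3 further fits were Enpp2, the enzyme autotaxin (50.1 ± 32.8 and 3.59 ± 0.15 CPM), Nes, which encodes nestin (32.7 ± 14.5 and 5.79 ± 0.88 CPM), and Nfe2l2, which encodes NRF2 (633 ± 94.6 and 1269 ± 6.98 CPM). The p53 targets Ccng1 (110 ± 30.3 and 491 ± 90.9 CPM), Ephx1 (68.0 ± 20.1 and 275 ± 7.66 CPM) and Zmat3 (31.4 ± 10.9 and 112 ± 21.7 CPM) were also among them. In edgeR's test no p53 target passed over the list alone between KO and WT dysplastic lines.

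EdgeR called 0 genes between KO and WT dysplastic lines, with 588 at an unadjusted p under 0.05, against 69 by DESeq2 and 101 by limma-voom. Of the G2/M genes 27 of 28 and of the S phase genes 24 of 30 had positive values here, with medians of 0.29 and 0.11, and none passed over the list alone. Camera called the G2/M list upward with the preset correlation (adjusted p 0.0018) and not the S phase list (0.26), and the adjusted p was 0.76 and 0.88 with an estimated one. The number of interferon genes that rose was 0 without line 565, 0 without line 752 and 1 without line 794, and 24 with line 801 left out. The 24 genes of the further fits became 45, 39, 1, 0, 2 and 357 without line 650, 1270, 565, 752, 794 or 801, and 1 in the 2 fits without the 6 libraries that stood apart.

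Dysplastic lines, compared with non-dysplastic lines as the mean of both genotypes, had higher interferon response and antigen presentation genes, a mean carried mostly by the KO lines. The interferon score was 3.88 and 3.13 in the dysplastic KO lines 794 and 801 and 2.26 and 2.19 in the dysplastic WT lines 565 and 752, against 2.20 in the non-dysplastic KO line 650, and no interferon gene passed among WT lines. Of 26 interferon genes 17 rose over the list alone and none fell, and of 13 antigen presentation genes 5 rose and none fell. Camera with an estimated correlation called neither list, as given below. Ifit1 read 6.06 ± 6.31 CPM in dysplastic and 0.72 ± 0.27 CPM in non-dysplastic lines, and Cd74, the class II invariant chain, 7.44 ± 4.43 and 1.46 ± 0.79 CPM (SD, n = 4 lines each). Dclk1 rose from 5.19 ± 3.11 to 35.6 ± 21.3 CPM, a log2 fold change of 2.69 ± 0.30 (SE). In edgeR's test its adjusted p, adjusted over the list alone, was 7.0e-04. Psca, a surface antigen listed with pit cell genes, fell by 1.55 ± 0.23 on the log2 scale. In the parietal cell list Ckb rose by 1.70 ± 0.38, Ckmt1 fell by 0.62 ± 0.13 and Slc9a4, a sodium-proton exchanger, fell by 0.46 ± 0.11. Trp53 itself differed by -0.06 ± 0.56.

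Among 49 genes taken from the 3 further fits for this comparison, 42 were higher and 7 lower. Enpp2 read 26.8 ± 32.9 CPM in dysplastic and 1.14 ± 1.07 CPM in non-dysplastic lines, Cp, which encodes ceruloplasmin, 79.1 ± 32.8 and 13.5 ± 14.6 CPM, and Sox7, a transcription factor, 8.50 ± 7.85 and 1.08 ± 0.40 CPM. Lower were Iyd, an iodotyrosine deiodinase (15.9 ± 8.26 and 44.4 ± 4.28 CPM), Ptgr1, a prostaglandin reductase (456 ± 126 and 1045 ± 310 CPM), and Nt5e, the ectonucleotidase CD73 (123 ± 24.8 and 209 ± 7.47 CPM; SD, n = 4 lines each). EdgeR called 0 genes, with 797 at an unadjusted p under 0.05, against 153 by DESeq2 and 138 by limma-voom. Camera called 13 of 27 lists with the preset correlation and 0 with an estimated one, the adjusted p then being 0.43 for interferon response and for antigen presentation. The exact permutation p of the score was 0.057 for interferon response (adjusted 0.15), 0.0286 for antigen presentation (adjusted 0.11), 0.31 for NRF2 and glutathione (adjusted 0.42) and 0.97 for p53 targets (adjusted 0.97). Lines 300 and 650 were male by Xist and Ddx3y counts and the other 6 lines female, so all dysplastic lines were female; with sex as a covariate 10 interferon genes rose. Without the libraries numbered 1, 2 interferon genes rose, and lines 300 and 650 then kept only their library that stood apart. Without the libraries numbered 2, edgeR called 134 genes, 30 higher and 104 lower. That setting took out 300-2 and 650-2, which stood apart, and kept such a library in every dysplastic line. The length shift was then confounded with dysplasia, so these 134 calls cannot be assigned to dysplasia. The 49 genes of the further fits became 13, 21, 290, 15, 5, 10, 82 and 218 without line 300, 1269, 650, 1270, 565, 752, 794 or 801, and 20 in the 2 fits without the 6 libraries.

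Split by genotype, dysplastic WT lines had more Dclk1 (18.5 ± 0.73 against 3.32 ± 0.76 CPM) and less Psca (87.6 ± 16.3 against 263 ± 4.13 CPM; SD, n = 2 lines each) than non-dysplastic WT lines, both called over their lists alone. Between dysplastic and non-dysplastic KO lines, 22 of 26 interferon genes and 6 of 13 antigen presentation genes rose over the list alone, at an adjusted p of 0.38 for each list in camera with an estimated correlation. Cd74 read 11.3 ± 0.20 and 1.86 ± 0.80 CPM, Dclk1 52.7 ± 13.9 and 7.06 ± 3.81 CPM, and Nr4a1, an immediate early gene, 35.4 ± 8.08 and 12.8 ± 1.40 CPM (SD, n = 2 lines each). From the 3 further fits, Stra6, a retinol-binding protein receptor, read 273 ± 74.3 and 38.3 ± 7.48 CPM, and Gyk, a glycerol kinase, 53 ± 5.01 and 118 ± 6.23 CPM. EdgeR called 0 genes in WT lines, with 156 at an unadjusted p under 0.05, against 4 by DESeq2 and 0 by limma-voom. In KO lines it called 0, with 1016 at an unadjusted p under 0.05, against 197 by DESeq2 and 239 by limma-voom. The 72 genes of the 3 further fits became 312, 0, 5, 13, 22 and 426 without line 650, 1270, 565, 752, 794 or 801.

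The KO effect in dysplastic lines was then set against that in non-dysplastic lines. With all lines, no gene was called for the difference by edgeR, DESeq2 or limma-voom, with 241 at an unadjusted p under 0.05 in edgeR. Without line 801, which leaves 1 dysplastic KO line, DESeq2 and limma-voom did call genes. All 26 interferon genes had a larger KO effect in the dysplastic lines, by a median of 1.73 on the log2 scale; camera called this with the preset correlation, and the adjusted p was 0.53 with an estimated correlation. Across genes, which are not independent replicates, the log2 fold changes of the KO effect in dysplastic and in non-dysplastic lines, estimates that share no line, had a Pearson correlation of 0.24 and a Spearman correlation of 0.01. For the 51 p53 targets these were 0.82 and 0.79. Over all genes the Pearson value was 0.42 without line 1269, 0.07 without line 650, 0.10 without line 801 and 0.11 without the 6 libraries that stood apart.

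Line 1270, the KO made ex vivo, was compared with line 650, the non-dysplastic KO made in vivo. Each arm is 1 line, so that spread came from the other lines and the comparison is of these lines. They also differed otherwise: line 650 was male and line 1270 female, 1 of the 2 libraries of line 650 and none of line 1270 was among the 6 that stood apart, Trp53 stood at 19.8% of WT in line 650 and 3.66% in line 1270, and line 650 had the highest fibroblast score of the 8 lines, 2.30 against 0.91 in line 1270, which moves with the mesenchymal genes below. All 18 members of the NF-kB and inflammatory cytokine list were lower in line 1270, and 6 fell over the list alone, among them Tnf (log2 fold change -2.17 ± 0.42, SE) and Tnfaip3 (-1.54 ± 0.36). Of the immediate early list 4 of 16 fell, with Fos at -1.64 ± 0.25, of the YAP target list 4 of 19, with the receptor kinase Axl at -3.76 ± 0.70, and of the mesenchymal transition list 3 of 13, with Fn1, which encodes fibronectin, at -2.46 ± 0.50. Col1a1, a collagen gene of the fibroblast list, was at -2.77 ± 0.52 and Vil1, which encodes villin, at -1.32 ± 0.24. Of the p53 targets 3 of 51 fell, with Phlda3 at -3.13 ± 0.62. All 28 G2/M genes had positive values, with a median of 1.03, and none passed over the list alone. EdgeR called 0 genes, with 953 at an unadjusted p under 0.05, against 191 by DESeq2 and 25 by limma-voom; without the 6 libraries that stood apart these were 190 and 5. Camera called 15 of 27 lists with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.19, and fry called 1 list, mesenchymal transition.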

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

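The tests on the share of cells that kept p53 in lines 650 and 801, on immune transcripts, on interferon genes without 6 libraries, in line 801 and by sex, and the genes, fibroblast and mesenchymal scores and Rn45s shares examined per line or library, were chosen after the results were seen.

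Several values lay far from the rest of their group, in 8 of the 57 sets of 4 to 10 values examined. Chance flags about 1 in 20 of independent sets, but these sets share lines and some of their genes were chosen after the values were seen, so that their number is not evidence of more than chance. Line 794 stood apart for the pit cell gene Gkn1, at 3760 CPM against 463 CPM in the nearest KO line and 67.2 CPM in the nearest dysplastic line, and for the mucin Muc5ac, at 461 CPM against 5.29 CPM in the nearest dysplastic line. Line 1270 had 185 CPM of Muc5ac against 8.54 CPM in the nearest non-dysplastic line. Line 650 had 18.2 CPM of Col1a1 against 2.90 CPM, and 4.86 CPM of Fstl1 against 0.58 CPM, in the nearest non-dysplastic lines. Library 752-3 had 0.87% of its counts on the ribosomal RNA gene Rn45s, against 0.21% in the nearest WT dysplastic library; other length-shifted libraries were raised as well, as given below. Library 794-2 had an NRF2 and glutathione score of 7.89 against 7.41 in the nearest dysplastic KO library. Outside the compared measurements, the Y-linked Ddx3y had 940 counts in line 300 and 544 in line 650, against at most 2 in the other 6 lines.

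The KO effect differed between dysplastic and non-dysplastic lines for 17 of 27 lists when camera's preset correlation was used, and for none with an estimated correlation, where the adjusted p of these 17 ran from 0.53 to 0.70. The median difference in log2 fold change was 1.73 for interferon response, 1.26 for endothelial cell, 1.12 for squamous forestomach cell, 0.87 for NF-kB and inflammatory cytokines, 0.64 for antigen presentation, 0.63 for glycolysis and hypoxia, 0.60 for immediate early, 0.59 for G2/M and mitosis, 0.55 for S phase and replication, 0.36 for Wnt targets, 0.36 for regenerative epithelium and YAP targets, 0.29 for DNA repair, 0.23 for unfolded protein and amino acid response, 0.18 for mucous neck cell and SPEM, -0.62 for NRF2 and glutathione, -0.95 for chief cell and -0.97 for endocrine cell genes.

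Lines 650 and 801 kept 19.8% and 16.1% of the WT level of Trp53. A candidate explanation is that cells which kept p53 made up part of these cultures. Then p53 targets that stood below 50% of WT in the other KO line of the same class should lie above it by about that share. Targets with a WT mean of at least 10 CPM were used. Over 9 such targets line 801 lay above line 794 by an implied share of 14.4% (quartiles 12.0% and 17.5%), and over 25 targets line 650 lay above line 1270 by 31.1% (quartiles 21.0% and 57.1%). Without that limit, an alternative added after the values were seen, the share was 14.8% over 14 targets for line 801 (quartiles 10.98% and 39.9%). For line 650 it was 31.9% over 28 targets (quartiles 21.4% and 56.4%). The 16.1% of Trp53 lay between the quartiles for line 801 in both settings. For line 650 the 19.8% lay below the lower quartile in both, so its targets stood higher than predicted. The implied share is the rise over the other line as a part of that line's distance from WT. Trp53 was not put on that scale, where its shares would be smaller than 19.8% and 16.1%. Gdf15 and Trp53cor1, 2 of the 14, were lower in line 801 than in line 794, and Tap1, 1 of the 28, was lower in line 650 than in line 1270. Of 50 targets with a WT mean of at least 1 CPM, only Ak1 lay below the 19.8% of Trp53 in line 650, at 13.9%. Taking the targets from lines 801 and 650 instead gave -14.2% for line 794 and -21.5% for line 1270, so the choice of low targets did not by itself make the shares positive; line-to-line differences in p53 targets for other reasons and a partly active allele stay open. The 2 lines also had the highest fibroblast scores of the 8 lines, 2.30 in line 650 and 1.84 in line 801 against 0.91 in line 1270 and 1.25 in line 794, and the highest mesenchymal transition scores, 4.57 and 4.63 against 3.11 and 4.27. Whether cells that kept p53 were epithelial or of another type, such as fibroblasts, was not tested and stays open.

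The libraries that stood apart, 6 in number, read low for long genes. After thinning all libraries to the smallest total 6 of the 6 kept the correlation. Thinning keeps the gene proportions of each library on average, so this outcome was close to fixed and does not decide on depth. Library 300-2 had 11.0e6 counts beside 11.2e6 in 300-1, and 565-3 had 11.4e6 beside 10.7e6 in 565-2. Libraries 650-2, 752-3, 794-3 and 801-3 each had the fewest counts of their line, so depth stays open. A trend on gene length is not the whole of it, because the median correlation between the 6 libraries was 0.80 before and 0.70 after a smooth length trend was removed. A sign of quality moved with them. Rn45s took 0.42%, 0.59%, 0.87%, 0.55% and 0.84% of counts in libraries 300-2, 650-2, 752-3, 794-3 and 801-3, against at most 0.19%, 0.31%, 0.16%, 0.26% and 0.16% in the other libraries of their lines, with 565-3 the exception at 0.21% and 0.21%. The 10 genes with the most counts took a larger share in each of the 6 than in the other libraries of its line, from 5.60% in 565-3 to 6.56% in 794-3. Whether RNA quality or library preparation differed was not tested further. The labels give no batch. Each of these libraries belongs to a different line and is the last-numbered library of that line, and lines 1269 and 1270 had none by this measure. As deviations were from the line mean, a shift shared by all libraries of a line would not be seen. With 2 libraries in a line, the values mirror each other and do not show which library moved. No biological explanation was tested, so the source stays open.

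Interferon response genes were higher in the dysplastic KO lines 794 and 801. Summed immune transcripts of line 794 were 0.78 times the mean of the WT dysplastic lines, so no rise in immune cells was seen there. The sum was 1.70 CPM, near the floor, which does not exclude such cells. For line 801 the ratio was 1.503, between the limits of 1.5 and 2 set for either reading. The margin was small and the limits were set after the values were seen, so immune cells cannot be told apart there. Against immune cells in line 801, the non-dysplastic WT line 1269 had 2.82 CPM of the same transcripts, beside 3.29 CPM in line 801, at an interferon score of 2.11 against 3.13, and the immune cell gene Ptprc was at 0.91 CPM in line 801 and 0.99 CPM in WT dysplastic line 752; these values lie near the floor and do not decide it. The length-shifted libraries are argued against by 18 genes that rose without them, and line 794 as the only source by 23 of 26 members above both WT dysplastic lines in line 801. Those members are not independent and come from 1 line. Without line 794 only 1 interferon gene rose over the list alone for KO in dysplastic lines. Lines 794, 801, 565 and 752 were all female, so sex cannot account for the difference between KO and WT dysplastic lines. For dysplastic against non-dysplastic lines, sex as the only source is argued against by a median difference of 1.22 on the log2 scale among female lines. That value pools KO and WT lines, and the interferon scores of the female WT lines were 2.26 and 2.19 in dysplastic lines 565 and 752 against 2.11 in line 1269. An effect of p53 loss together with dysplasia, and a difference between these lines in culture or origin, stay open and untested.

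The 8 lines were split into 4 and 4 in the 34 ways that could be fitted beside the other factor. For the 2 counts of list members that were run, with all 8 lines, the real split gave the largest count. As 1 of 34 is the smallest share possible and 10 counts were run over splits without adjustment, this does not exclude chance. With additive effects of genotype and dysplasia, a model that differs from that of the report, the real split gave 19 p53 targets for KO against WT, and the highest other split 11, so that 1 of the 34 was as large. For dysplastic against non-dysplastic lines the real split gave 14 interferon genes and the highest other 3, again 1 of the 34. In the model of the report the p53 targets numbered 17, and 5, 6, 8 and 9 without line 565, 1269, 1270 or 794 and 10 with sex as a covariate, and the interferon genes 17, and 2 without the libraries numbered 1; the splits were not repeated in that model or those settings. The exact permutation p was 0.0286 for the p53 score and 0.057 for the interferon score in dysplasia, and 0.11 and 0.15 after adjustment. The 19 interferon genes for KO in dysplastic lines compare 2 lines with 2 and were not run over splits. Chance could also not be excluded for the numbers of lists called or for the counts over all genes of DESeq2 and limma-voom, where other splits gave as many. With edgeR the real count was 0 in both comparisons, which every one of the 34 splits reaches by construction, so the splits say nothing there; the highest others were 37 and 1. With DESeq2, 8 splits gave at least the 90 genes of KO against WT (highest other 1881) and 6 at least the 145 of dysplasia (highest other 1831). With limma-voom 8 gave at least 110 (highest other 810) and 5 at least 189 (highest other 428). For lists called with the preset correlation, 24 splits reached the 12 lists of KO against WT (highest other 17) and 20 the 12 of dysplasia (highest other 19). The split with 1881 genes set lines 300, 650, 752 and 794 against the rest, a structure of the lines that follows neither factor.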

How the results depend on the processing

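Fits without the 6 length-shifted libraries, with a library term, with sex of the line as a covariate, and the 3-fit counts were chosen after seeing the data. Lists of calls over all genes are given in the order KO against WT as a mean, in non-dysplastic and in dysplastic lines, then dysplastic against non-dysplastic as a mean, in WT and in KO lines, then ex vivo against in vivo. The main edgeR test called 0 in each, as did RLE scaling. The count for the difference between KO effects was 0 in each single-tool alternative, among which only edgeR was run with a line left out. The 3-fit count for it was 0 with all lines. Without line 801, which leaves 1 dysplastic KO line, DESeq2 and limma-voom did call genes for that difference. DESeq2 called 74, 6, 69, 153, 4, 197 and 191 genes. Libraries as samples without a replicate block gave 212, 0, 420, 394, 6, 560 and 123, and with the replicate block 213, 0, 448, 428, 1, 580 and 174, so pairing by the block moved the count by over 1.5 times for dysplasia in WT lines and for no other comparison; treating libraries as samples also made 97 false calls in the simulation with no changed gene. Limma-voom with correlated lines called 63, 5, 101, 138, 0, 239 and 25, and with the library term 43, 2, 37, 92, 0, 139 and 12. Without the length-shifted libraries DESeq2 called 64, 15, 73, 259, 2, 468 and 190, limma-voom 14, 0, 1, 20, 0, 73 and 5, and edgeR 0 in each. With sex as a covariate edgeR called 1 gene in each of the 3 dysplasia comparisons, and without a filter 1 gene for ex vivo against in vivo. The cause of these differences was not tested.

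With a line left out, edgeR called few or no genes for KO against WT as a mean or in dysplastic lines. Leaving out a replicate number gave edgeR counts of 0 to 134 for dysplasia as a mean, the highest without the libraries numbered 2. There every dysplastic line kept its length-shifted library and no non-dysplastic line did, so these calls cannot be told apart from the shift. The 3-fit counts, 24, 24, 49 and 72 for KO as a mean, KO in dysplastic lines, dysplasia as a mean and dysplasia in KO lines, ranged over 4 to 154, 0 to 357, 5 to 290 and 0 to 426 when a line was left out, and were 14, 1, 20 and 69 in 2 fits without the length-shifted libraries. The p53 targets called over the list alone ranged from 5 to 28, with 27 under 5 group means and 10 with sex as a covariate. Interferon genes ranged from 0 to 24 for KO in dysplastic lines, and from 2 to 22 for dysplasia as a mean, with 10 there when sex was a covariate. The p53 score difference ranged from -0.89 to -0.66 and its unadjusted exact permutation p was 0.0286 in the main setting and in each alternative except without line 1269, where it was 0.057; adjusted over the 8 score tests the main p was 0.11, and the adjustment was not repeated in the alternatives. Trp53 in KO lines was 11.1% of WT and ranged from 8.29% to 13.6%. Camera lists numbered 11 and 13, ranged over 10 to 17 and 11 to 18, and fell to 0 and 0 with an estimated correlation and to 0 and 0 with fry. The fold change correlation of 0.24 was 0.0102 as Spearman's, 0.105 without the length-shifted libraries, and ranged from 0.0687 to 0.423 without a line.

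Trp53 between dysplastic and non-dysplastic lines lay near 0 and changed sign. As a mean it was 0.0411 with limma-voom, 0.0462 with the library term, 0.17 with 5 group means, 0.44 with sex as a covariate, and 0.0542, 0.0419 and 0.16 without the length-shifted libraries in edgeR, DESeq2 and limma-voom. In WT lines it was -0.0117 with libraries as samples and no replicate block, -0.00380 with limma-voom, -0.00569 with the library term and -0.00760 with limma-voom without the length-shifted libraries. In KO lines it was 0.0861, 0.10, 0.33 and 0.57 with limma-voom, the library term, 5 group means and sex, and 0.0796, 0.0550 and 0.32 without the length-shifted libraries. Leaving out lines or replicate numbers moved these from -0.59 to 0.78, from -0.22 to 0.33 and from -1.20 to 1.54. With libraries at 5.67e6 counts or more, depth limits mainly genes near 1 CPM, such as Krt5.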

Other observations

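Gastric lineage genes differed widely between lines of one group. All genes in this part were chosen after their values were seen, and no test was made. Tff2, a mucous neck cell peptide, was at 1123, 1006, 828 and 591 CPM in lines 300, 650, 752 and 794 and at 15.1, 42.1, 208 and 121 CPM in lines 1269, 1270, 565 and 801. The proliferation marker Mki67 was at 305, 200, 273 and 287 CPM in the former lines and at 655, 484, 355 and 336 CPM in the latter. Gif, the intrinsic factor gene of chief cells in mice, ran from 2.83 CPM in line 794 to 609 CPM in line 1270. Acta2, which encodes smooth muscle actin, was at 104, 58.2 and 55.4 CPM in lines 801, 752 and 650, and at 0.95 CPM in line 794.

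Mgmt, the DNA repair enzyme that removes alkyl groups from guanine, was low in 2 of the KO lines. It read 0.06 CPM in line 1270 and 0.03 CPM in line 794, 3.10 CPM in line 801 and 6.72 CPM in line 650, against 10.7 to 13.6 CPM in the WT lines 300, 1269, 565 and 752 (in that order 10.97, 13.4, 10.7 and 13.6 CPM). Cdkn1a, which encodes the p53-activated inhibitor p21, was at 32.1 CPM in line 1270 and 95.8 CPM in line 801, but at 196 CPM in line 650 and 211 CPM in line 794, where the WT line 300 had 224 CPM. Eda2r, another p53 target, was at 0.16, 0.49, 7.73 and 16.9 CPM in lines 1270, 794, 801 and 650, and at 33.4 CPM or more in the WT lines.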
